A study of Homo sapiens with 6 samples.

How the data were processed

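RNA from cultured Huh-7.5 cells, a human hepatoma line, was measured with Affymetrix whole-transcript arrays of the Human Gene 1.0 ST type, which read each gene with probe sets spread over its exons. The 6 arrays formed 3 groups of 2, mock (0.1% ethanol), calcitriol (10 nM) and calcipotriol (10 nM), all collected after 12 h. The sample titles name ethanol for mock only and no solvent for the ligand groups. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was purified on columns, a small amount was amplified with a whole transcriptome kit, and the product was fragmented and labelled with biotin. The labels do not state whether the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

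The table deposited by the authors holds 1 value per probe set and array, read here as log2 values because they lie between 5.43 and 14.0 as log2 values of a 16-bit scanner do. The log base, the background correction, the summarisation and the normalization behind the deposited log2 values are not given in the sources used here, so every fold change below rests on the assumption of base 2. Some array-specific scaling was left in the deposited values, since their standard deviation over all probe sets ran from 0.753 in calcitriol replicate 2 to 1.15 in mock replicate 1, and their lowest value from 5.43 in mock replicate 1 to 5.96 in calcitriol replicate 2. By the rule set before the data were examined, arrays with unlike distributions were quantile normalized, and this gives the values below. Quantile normalization makes the distribution of values equal on all arrays, so it removes any change that would shift most genes together.

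The table has 32321 probe sets with 0 missing values. The array's annotation gives 1 gene symbol for 19158 of them, several for 1388 and none for 11775. Symbols were brought up to date through Entrez numbers with RefSeq gene names of assembly GRCh38.p14, used for names only, which matched 19128 probe sets. Probe sets with several symbols or none were not tested. For each gene the probe set with the highest mean over the 6 arrays was kept, which left 18404 genes. In 637 genes with several probe sets the choice matters, since the probe sets of 328 of them differed in sign for calcitriol against mock, 284 for calcipotriol against mock, 304 between the ligands and 303 for the mean of both. No filter on dim probe sets was used, and no detection call was analysed here. Genomic coordinates are not given because the annotation names no genome build.

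Differences between group means were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust). All 6 arrays entered 1 fit with 3 residual degrees of freedom, to which the prior added 3.02. The tests were two-sided, with Benjamini-Hochberg adjustment over the 18404 genes and a threshold of 0.05, and intervals are 95% confidence intervals from the same fit. The 4 contrasts were calcitriol against mock, calcipotriol against mock, calcipotriol against calcitriol, and the mean of both ligands against mock. Errors of differences are standard errors (SE), and errors of group means are standard deviations (SD) of 2 arrays. The number of arrays limits the precision.

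Before the data were examined, 27 gene lists were fixed: VDR target genes, vitamin D metabolism and transport, drug metabolism and transport, bile acid metabolism, cholesterol synthesis and SREBP2 targets, fatty acid and triglyceride synthesis, fatty acid oxidation and PPARA targets, glucose metabolism, interferon-stimulated genes, NF-kB targets and cytokines, acute phase proteins, cell cycle and proliferation, p53 targets and growth arrest, NRF2 targets and oxidative stress, unfolded protein response and ATF4 targets, hypoxia and HIF1A targets, hepatocyte markers, calcium and mineral transport, mesenchymal and TGF-beta targets, hepatitis C virus host factors, immediate-early and heat shock genes, stellate cell and fibroblast markers, endothelial markers, macrophage and lymphocyte markers, cholangiocyte and keratinocyte markers, reference genes, and replication-dependent histones. Of their 576 entries, 527 were measured. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation. The version with an estimated correlation was not tried on simulated data, so its power to call a list here is unknown. Limma's fry tested whether a list's genes moved on balance one way, or changed in either direction. Members past 0.05 when adjusted over the list alone are given as such.

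The named genes followed a rule also set beforehand. For each contrast and direction it takes the 12 genes of largest fold change among those past the threshold whose arrays separate completely between the groups. Where fewer passed, it takes the separating genes of smallest unadjusted p, which are then given as values that did not pass. List members were named where they passed, and otherwise up to 4 per list with the smallest unadjusted p. CYP24A1 and VDR are always named. A few other genes, marked as such where they appear, were named because they made up a count of 5 or fewer.

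The correlation across genes between the fold changes of both ligands is inflated by the mock arrays they share. It was therefore set beside 100 simulations of unchanged groups against shared controls with the replicate variance of each group. The variances drawn in these simulations and in the test on simulated data were revised after a first output was seen, because they had been set too low, and the sign of the covariance difference for the shared calcitriol arrays stayed negative. Because the replicate variance of each group rests on 1 pair of arrays, the covariance for the shared calcitriol arrays is also set against the lowest and highest of the 3 groups' replicate variances, a wider bound chosen after its value was seen. Medians of lists were also set against 10000 random lists matched on brightness (each member replaced by a gene within 100 ranks of its mean value).

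The fitting steps were tested on simulated data with the real genes and known changes among 18404 genes. A change of 1 on the log2 scale was recovered for 94.0% of changed genes in calcitriol against mock, 100% in calcipotriol against mock, 94.0% in calcipotriol against calcitriol and 98.5% in the mean of both ligands. For a change of 0.5 the shares were 65.7%, 76.1%, 64.2% and 79.1%. The simulations changed many genes at once, and a real effect on fewer genes meets a harsher adjustment. They also changed only genes brighter than the median gene and gave every group the same spread. In the real data the replicate variance of a group mean was 0.00681 in calcitriol, 0.00319 in mock and 0.00259 in calcipotriol. The shares recovered may therefore overstate what the real arrays can find.

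The alternatives tried were the values as deposited, median centring, no dim genes, the mean of a gene's probe sets, all probe sets as separate features, a variance trend, a robust prior, array weights, only the groups compared, the replicate number as a block, each array left out in turn, an unadjusted threshold with a minimum fold change, and for lists the estimated correlation and fry. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.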

Results

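Gene expression was measured in Huh-7.5 cells, a human hepatoma line often used to grow hepatitis C virus. The cells had 12 h of mock treatment or of 1 of a pair of ligands of the vitamin D receptor (VDR). Calcitriol is the hormonally active form of vitamin D. Calcipotriol is a synthetic analog with an altered side chain that carries a cyclopropyl ring. Both were given at 10 nM, and the mock cultures received 0.1% ethanol, with 2 arrays in each of the 3 groups. The comparisons ask which genes respond to each ligand and whether the ligands differ at this dose and time.

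**Figure D1:**
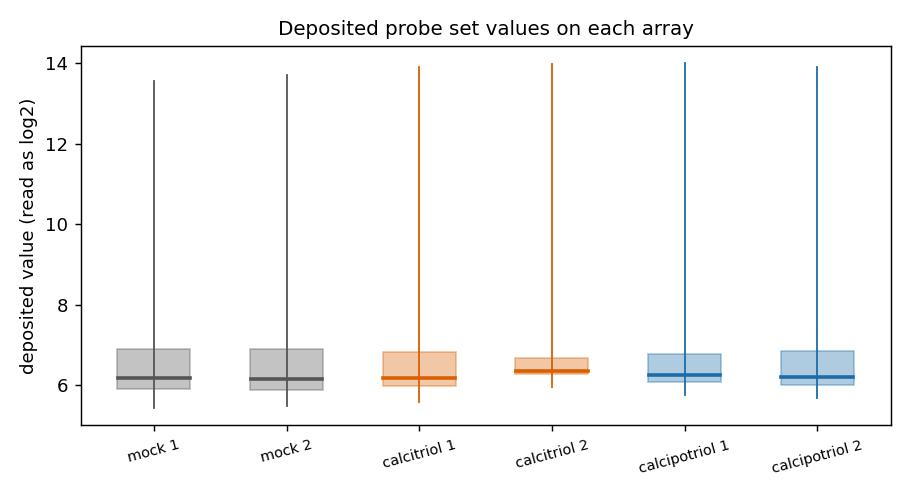
Range of the deposited probe set values (read as log2) on each of the 6 arrays, with the thin line from lowest to highest value, the box from the lower to the upper quartile and the bar at the median. The box of calcitriol replicate 2 is the narrowest, from 6.26 to 6.67, and the box of mock replicate 1 runs from 5.89 to 6.90.

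The deposited arrays had medians between 6.15 and 6.36 and unlike spreads. After quantile normalization, the mean correlation of an array with the others was 0.983 for calcitriol replicate 2 and between 0.987 and 0.991 for the other 5. The replicates differed by a median of 0.0515 on the log2 scale in the mock group, 0.0907 in the calcitriol group and 0.0557 in the calcipotriol group. The median SE of a pairwise difference was 0.0611, and the median 95% interval reached 0.149 to either side, or 1.11-fold.

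CYP24A1, the enzyme that inactivates calcitriol and the best known gene induced through VDR, went against the calcitriol label. Its log2 value was 7.98 ± 0.64 (SD, n = 2) in the arrays labelled mock, 6.13 ± 0.07 (SD, n = 2) in the arrays labelled calcitriol and 8.19 ± 0.27 (SD, n = 2) in the arrays labelled calcipotriol. The single arrays read 7.53 and 8.43 in mock, 6.08 and 6.18 in calcitriol, and 8.01 and 8.38 in calcipotriol, with the median of all probe sets at 6.21. No background value was analysed here, so the signal of CYP24A1 in calcitriol is not shown to lie above background, and its measured differences from calcitriol may understate the true ones. The same holds for SNORD13P1 in calcitriol and for CGA and SLCO1B3 in mock and calcitriol, and PCDHA3 lay below that median in all 3 groups. SLC30A10, a manganese exporter and another known VDR target, had the same order, with 7.57 ± 0.07 (SD, n = 2) in mock, 7.15 ± 0.06 (SD, n = 2) in calcitriol and 7.66 ± 0.10 (SD, n = 2) in calcipotriol. VDR itself read 6.39 ± 0.01 (SD, n = 2), 6.41 ± 0.03 (SD, n = 2) and 6.28 ± 0.02 (SD, n = 2) in the same order of groups. Because of CYP24A1, groups are called by their labels throughout, and every direction below holds for arrays labelled so.

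**Figure D2:**
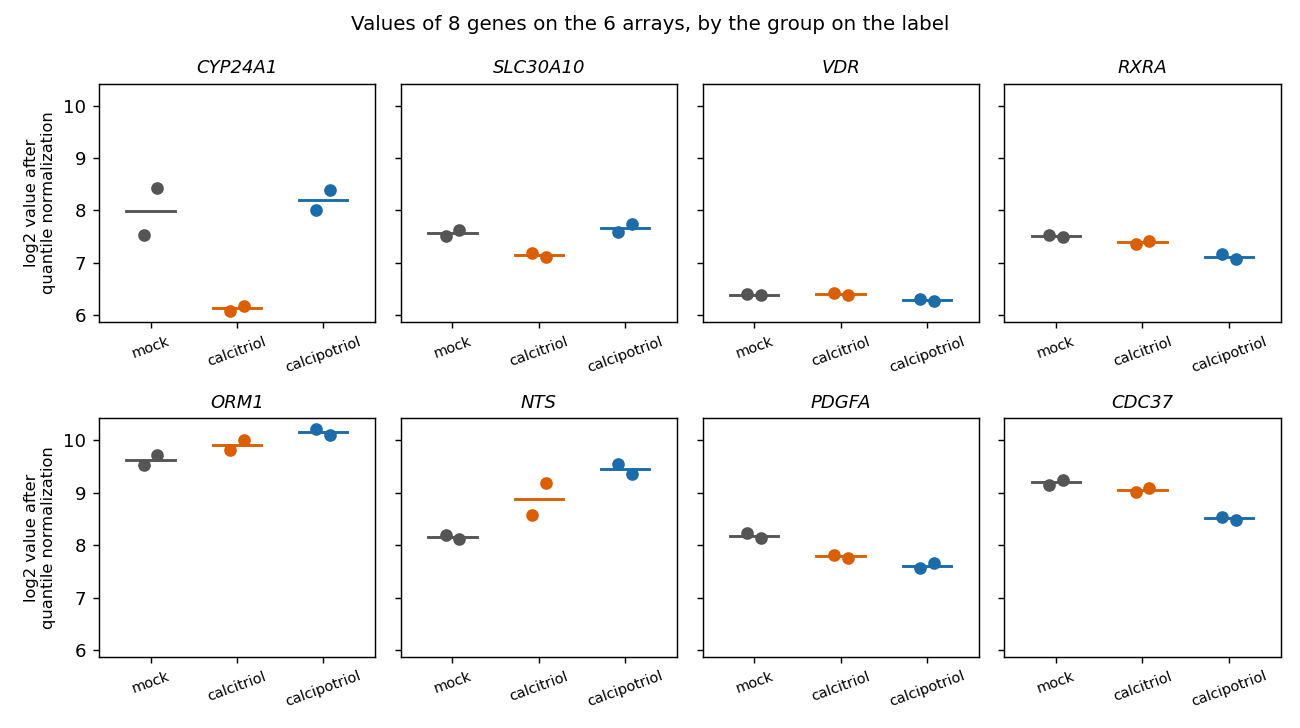
Quantile-normalized log2 values of 8 genes on the 6 arrays, with 1 point per array and a bar at the mean of the 2 arrays of each labelled group. CYP24A1 reads 6.08 and 6.18 in the arrays labelled calcitriol and between 7.53 and 8.43 in the other 4, while NTS, PDGFA and CDC37 have their most distant values from mock in the arrays labelled calcipotriol.

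Between the arrays labelled calcitriol and mock, the measured difference of CYP24A1 was -1.85 (SE 0.29, 95% interval -2.55 to -1.15), of open size because its calcitriol signal may be background. SLC30A10 was at -0.42 (SE 0.07). Both were lower in both arrays labelled calcitriol than in both mock arrays, opposite to a response to a VDR ligand as the labels stand. PDGFA, which encodes a chain of the growth factor PDGF, was at -0.39 (SE 0.06), and VDR at 0.02 (SE 0.05), or -0.06 with median centring. None of these passed the threshold over all genes (limma, adjusted p = 0.932 for CYP24A1, SLC30A10 and PDGFA, 0.959 for VDR).

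The other genes named by the rule for calcitriol against mock lay between 0.21 and 0.48 or between -0.55 and -0.26, each with an adjusted p of 0.932. The higher ones were PARGP1, FN3KRP, MEST (an imprinted gene), CST4, GSKIP, SNORD116-6 (a small nucleolar RNA), GNAT2, MORF4L1, RRN3 (an RNA polymerase I factor), EI24, CLRN3 and NDFIP1. The lower ones were SEPT5-GP1BB, PCDHA3, AP1G2, H2AC15, MAPK7, ZFAND2B, CAVIN1 (a coat protein of caveolae), SIPA1L3 and DNM2 (dynamin, which pinches off vesicles). PARGP1 was at 0.41 (SE 0.05), or 0.20 as the mean of its 2 probe sets and 0.23 with median centring, and DNM2 at -0.34 (SE 0.07). SEPT5-GP1BB was at -0.55 (SE 0.09), or -0.27 as the mean of its probe sets. PARGP1 is a pseudogene, SEPT5-GP1BB a readthrough transcript, and both can share probe signal with close copies. The sign of FN3KRP, MEST, EI24 and NDFIP1 turned with median centring, and that of SNORD116-6, MORF4L1 and CLRN3 also with the values as deposited. A total of 4 genes had an unadjusted p under 0.01 and at least 1.5-fold, CYP24A1, DHX16 (-0.74, SE 0.19), SNORD13P1 (-0.64, SE 0.14) and NTS (0.73, SE 0.19), of which DHX16, SNORD13P1 and NTS are named after their values were seen. DHX16 was at -0.42 as the mean of its probe sets.

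None of the 27 lists passed between calcitriol and mock, and the smallest adjusted p was 0.328, for hepatocyte markers. The direction of cell cycle and proliferation depended on the setting, as the list passed with higher values in calcitriol without mock replicate 2 (0.0317) and with lower values with the values as deposited (8.35e-07) and with median centring (0.00242). Under both of these scalings, interferon-stimulated genes also passed with higher values, and with lower values the lists of cholesterol synthesis, fatty acid synthesis, p53 targets, unfolded protein response, hepatocyte markers, hepatitis C virus host factors, immediate-early genes and reference genes. Of 43 measured VDR target genes, 0 passed over all genes, and CYP24A1 and SLC30A10 (each at 0.0227) passed when adjusted over the list alone. In vitamin D metabolism and transport, CYP24A1 passed adjusted over the list alone (0.00890) and CYP27A1, a sterol hydroxylase, was at -0.16 (SE 0.05). In calcium and mineral transport, SLC30A10 passed adjusted over the list alone (0.0253). No member of the other 24 lists passed in this way. Among drug metabolism genes, CYP1A1 was at -0.43 (SE 0.11) and ABCC3, a drug exporter, at -0.19 (SE 0.05). FGFR4, a receptor that controls bile acid synthesis, was at -0.31 (SE 0.10), DGAT1, which makes triglycerides, at -0.26 (SE 0.06), and the matrix protein gene CCN1 at -0.25 (SE 0.05). The albumin gene ALB was at 0.17 (SE 0.06) and CDK1, a kinase of mitosis, at 0.17 (SE 0.05), both turning sign with the values as deposited or median centred (ALB -0.42 and -0.53, CDK1 -0.07 and -0.19).

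Over all genes, limma called 0 between calcitriol and mock. An unadjusted p under 0.05 was reached by 789 genes, 397 higher and 392 lower, where 920 are expected by chance. The split was 777 higher and 1331 lower with the values as deposited, and 839 and 1578 with median centring. Complete separation of the arrays held for 30.9% of genes against 33.3% by chance. With a variance trend in the fit, 2 genes passed, CYP24A1 and PCDHA3 (adjusted p = 0.0280 and 0.04996).

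Between the arrays labelled calcipotriol and mock, NTS, which encodes the peptide neurotensin, was at 1.29 (SE 0.19), with 9.45 ± 0.13 (SD, n = 2) in calcipotriol and 8.15 ± 0.05 (SD, n = 2) in mock. APOH, a plasma glycoprotein made by hepatocytes, was at 0.54 (SE 0.07) and IDI1, an enzyme of the sterol pathway, at 0.42 (SE 0.05). CDC37, a co-chaperone of HSP90 for kinases, was at -0.69 (SE 0.06), SIPA1L3 at -0.80 (SE 0.08) and the tubulin gene TUBB2A at -0.66 (SE 0.06). CYP24A1 differed by 0.21 (SE 0.29, 95% interval -0.49 to 0.91) and VDR by -0.10 (SE 0.05), and the sign of CYP24A1 turned with median centring (-0.03) or without mock replicate 1 (-0.23). None passed over all genes (limma, adjusted p = 0.198 for NTS, APOH, IDI1, CDC37, SIPA1L3 and TUBB2A, 0.896 for CYP24A1 and 0.519 for VDR).

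The remaining higher genes of the rule in calcipotriol against mock, between 0.32 and 0.45, were AGR2 (a disulfide isomerase), PARGP1, CENPW (a kinetochore protein), SAT1 (which acetylates polyamines), ELOC, LAMP2 (a lysosomal membrane protein), GGH, NDUFB3 (a subunit of respiratory complex I) and PFDN4. The remaining lower ones, between -0.71 and -0.38, were STARD10 (a lipid transfer protein), DNM2, PDGFA, BIN1, LASP1, ANKRD52, DGAT1, SLC29A4 (a monoamine transporter) and MED15 (a Mediator subunit). DNM2 was at -0.66 (SE 0.07), PDGFA at -0.57 (SE 0.06) and SLC29A4 at -0.71 (SE 0.09). All had adjusted p between 0.198 and 0.204, and all lay on the same side in both arrays of the group against both mock arrays. ELOC, TUBB2A, LASP1 and PARGP1 have 2 probe sets each, of which the brighter was used, and the mean of both gave 0.15, -0.34, -0.32 and 0.23.

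Acute phase proteins were the only list past the threshold in calcipotriol against mock. Of its 21 measured genes, 17 had a positive difference, 0 passed over all genes and ORM1 passed adjusted over the list alone (0.0294), with camera's adjusted p = 0.0218 at the preset correlation and adjusted p = 0.653 with an estimated correlation. The plasma proteins ORM1 and ORM2 were at 0.54 (SE 0.10) and 0.52 (SE 0.15), the protease inhibitor A2M at 0.51 (SE 0.16) and the fibrinogen chain FGG at 0.33 (SE 0.12). The call was also lost with the values as deposited (0.423), with median centring (0.507), and without mock replicate 2 (0.0525), calcipotriol replicate 1 (0.0544) or calcipotriol replicate 2 (0.0696). The list still passed without dim genes (0.0172) and with the replicate number as a block (0.0187). Its call was also not lost without mock replicate 1 or either calcitriol array. ORM1 and ORM2 are near-identical copies whose probes may not tell them apart.

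Single members of other lists passed in calcipotriol against mock only when adjusted over the list alone, and these lists as wholes did not pass with quantile normalization. With the values as deposited, hepatitis C virus host factors (0.000296), cell cycle (0.00223), immediate-early genes (0.000296), unfolded protein response (0.00693) and p53 targets (0.0325) passed with lower values in calcipotriol than in mock. With median centring hepatitis C virus host factors (0.0438), immediate-early genes (0.00375) and p53 targets (0.0438) did. In cholesterol synthesis and SREBP2 targets, 4 of 18 passed in this way, with IDI1 and SC5D (0.35, SE 0.06), both enzymes of sterol synthesis, and the sterol carrier STARD4 (0.25, SE 0.06) higher and SREBF2, which encodes the pathway's transcription factor, lower (-0.34, SE 0.06). In hepatitis C virus host factors, 4 of 19 passed, DGAT1 (-0.50, SE 0.06), the RNA-binding protein gene PTBP1 (-0.62, SE 0.14) and the entry factor EPHA2 (-0.35, SE 0.09) lower and cyclophilin A, PPIA, higher (0.30, SE 0.07). In cell cycle and proliferation, 3 of 32 passed, with cyclin D1, CCND1 (-0.49, SE 0.08), and CDC20 (-0.23, SE 0.05) lower and CDK1 higher (0.24, SE 0.05). In hepatocyte markers, APOH and ALB (0.34, SE 0.06) passed, 2 of 26.

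One member each passed adjusted over the list alone in 7 further lists. These were RXRA, the partner of VDR in DNA binding (-0.39, SE 0.06), in vitamin D metabolism, FGFR4 (-0.66, SE 0.10) in bile acid metabolism, DGAT1 in fatty acid and triglyceride synthesis, ACADVL, an enzyme of fatty acid oxidation (-0.45, SE 0.06), in PPARA targets, the chemokine CCL20 (0.47, SE 0.08) in NF-kB targets, CCN1 (-0.39, SE 0.05) in mesenchymal genes and the keratin KRT19 (-0.63, SE 0.12) among cholangiocyte markers. In reference genes, 2 of 11 passed, B2M (0.29, SE 0.07) and PPIA, both often used as constant controls. No member passed in this way in the lists of VDR targets, drug metabolism, glucose metabolism, interferon-stimulated genes, p53 targets, NRF2 targets, unfolded protein response, hypoxia, calcium and mineral transport, immediate-early genes, stellate cell, endothelial, or macrophage and lymphocyte markers, or histones.

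Over all genes, limma called 0 between calcipotriol and mock. An unadjusted p under 0.05 was reached by 1901 genes, 825 higher and 1076 lower, where 920 are expected by chance. The split was 63 higher and 1285 lower with the values as deposited, and 211 and 1333 with median centring. Complete separation held for 47.3% of genes against 33.3% by chance. An unadjusted p under 0.01 with at least 1.5-fold held for 29 genes, 3 higher and 26 lower. In fry, 0 lists moved on balance one way and 12 changed in either direction, a test that does not set a list against other genes.

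In the direct comparison of the ligands, at matched dose and time, CYP24A1 was higher in the arrays labelled calcipotriol than in those labelled calcitriol by a measured 2.06 (SE 0.29, 95% interval 1.37 to 2.76), with the calcitriol signal not shown to be above background, and SLC30A10 by 0.52 (SE 0.07, 95% interval 0.34 to 0.69). Neither passed over all genes (limma, adjusted p = 0.590 for each). CEP170, a centrosomal protein gene, was at 0.73 (SE 0.10), or 0.45 as the mean of its 2 probe sets, LAMP2 at 0.38 (SE 0.05) and CPM, a carboxypeptidase gene, at 0.42 (SE 0.07). CDC37 was at -0.54 (SE 0.06, 95% interval -0.68 to -0.41) and BIN1 at -0.45 (SE 0.06). VDR was at -0.12 (SE 0.05, 95% interval -0.24 to -0.01), and RXRA at -0.28 (SE 0.06).

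The remaining named genes of calcipotriol against calcitriol, all with an adjusted p of 0.590, were MTND2P28 (a pseudogene of a mitochondrial gene, open to shared signal), PFDN4, FAF2, APOH, GGH, CGA and MAPKAPK5-AS1 on the higher side, between 0.28 and 0.56. On the lower side, between -0.47 and -0.26, they were STARD10, CDC20, LETM1, ACAA1, ANKRD52, DPP3, SMARCB1 (a subunit of the SWI/SNF complex), DDX49, TUBB2A and GRK6. APOH was at 0.39 (SE 0.07) and FAF2 at 0.52 (SE 0.09), or 0.28 as the mean of its 2 probe sets, and the sign of CDC20 and TUBB2A turned with median centring (0.04 and 0.05). An unadjusted p under 0.01 with at least 1.5-fold held for 5 genes, CYP24A1, CEP170, NDUFV1 (-0.67, SE 0.15), HMGA1 (-0.64, SE 0.15) and ADRM1 (-0.61, SE 0.14), the last 3 named after their values were seen. HMGA1 was at -0.38 as the mean of its probe sets.

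Between the ligands, 3 lists passed camera with higher values in the arrays labelled calcipotriol, VDR target genes, drug metabolism and transport, and acute phase proteins, each with adjusted p = 0.0478 and each with adjusted p = 0.470 with an estimated correlation. The estimates, -0.0073, -0.0239 and -0.0185 in this order, lay below the preset 0.01. A higher correlation within the lists was therefore not what ended the calls. The lists overlap, since ABCB1 is also a VDR list member, and so are ORM1 and ORM2 of the acute phase list. These calls are therefore not independent of each other. Of 43 VDR target genes, 27 had a positive difference, 0 passed over all genes and 2, CYP24A1 and SLC30A10, passed adjusted over the list alone. Of 26 drug metabolism genes, 17 were positive and 0 passed either way, with the exporters ABCB1 (0.29, SE 0.08) and ABCC2 (0.16, SE 0.06), the uptake carrier SLCO1B3 (0.18, SE 0.05) and the xenobiotic receptor AHR (0.15, SE 0.06) of smallest p. Of 21 acute phase genes, 14 were positive and 0 passed either way, with the fibrinogen chains FGG (0.38, SE 0.12) and FGB (0.17, SE 0.07), the complement factor CFB (0.28, SE 0.09, or 0.11 as the mean of its probe sets) and ORM1 (0.25, SE 0.10) of smallest p. Without calcitriol replicate 1 no list passed (adjusted p = 0.812 for acute phase, 0.710 for VDR targets and 0.555 for drug metabolism), nor did any without either calcipotriol array. Without mock replicate 1, VDR targets (0.0502) and drug metabolism (0.0714) did not pass, and without mock replicate 2 drug metabolism (0.0714) did not. Drug metabolism also lost its call with the values as deposited (0.137) and with median centring (0.0584). VDR targets (0.00715 and 0.0137) and acute phase proteins (9.61e-06 and 0.00232) kept theirs under these scalings, where reference genes also passed. None of the 3 calls was lost without calcitriol replicate 2, a fit that leaves 1 array in that group. Without dim genes, acute phase proteins (0.0463) passed, VDR targets (0.0731) and drug metabolism (0.299) did not, and glucose metabolism passed with lower values in calcipotriol (0.0463). Without CYP24A1 and SLC30A10, camera's adjusted p was 0.280 for the VDR list, 0.0701 for drug metabolism and 0.0676 for acute phase proteins. No list passed in this alternative, which was chosen after seeing the data. With the replicate number as a block no list passed either, and in fry none moved on balance one way.

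The other lists did not pass between the ligands with quantile normalization. With the values as deposited and with median centring, 7 of them passed with higher values in calcipotriol, cholesterol synthesis (3.57e-05 and 0.00232), cell cycle (1.22e-05 and 0.00232), hepatocyte markers (0.000329 and 0.00232), fatty acid synthesis (0.000548 and 0.00232), NRF2 targets (0.00189 and 0.035), unfolded protein response (0.00189 and 0.0141) and reference genes (9.61e-06 and 0.00232). Fatty acid synthesis also passed without calcitriol replicate 2 (0.00544). Adjusted over the list alone, single members passed in vitamin D metabolism (CYP24A1 and RXRA), PPARA targets (ACADVL, at -0.32, SE 0.06), cell cycle (CDC20), hepatocyte markers (APOH) and calcium transport (SLC30A10). Over all genes limma called 0, and 1450 had an unadjusted p under 0.05, 656 higher and 794 lower, where 920 are expected by chance. That split was 92 and 7 with the values as deposited, and 50 and 8 with median centring. With a variance trend in the fit, CYP24A1 alone passed (adjusted p = 0.00837). The median interval of 0.149 to either side leaves room for differences of that size between the ligands in most genes, so the data do not show that the ligands act alike.

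**Figure D3:**
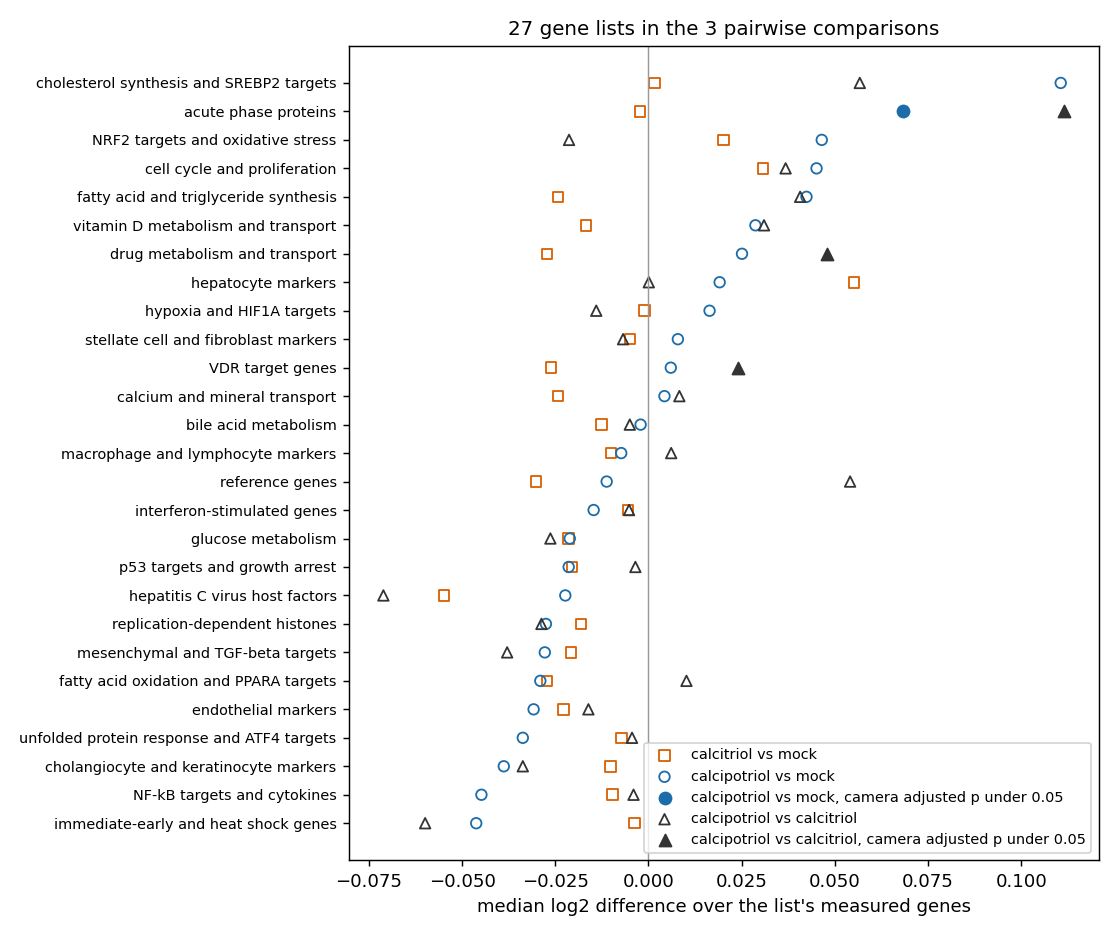
Median log2 difference over the measured genes of each of the 27 lists (rows) in 3 comparisons, with squares for calcitriol minus mock, circles for calcipotriol minus mock and triangles for calcipotriol minus calcitriol, filled where camera's adjusted p was under 0.05. The filled symbols are acute phase proteins in calcipotriol against mock (median 0.0683) and against calcitriol (0.112), drug metabolism (0.0479) and VDR targets (0.0239).

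For the mean of both ligands against mock, which uses 4 treated arrays, NTS was at 1.01 (SE 0.16), PARGP1 at 0.38 (SE 0.04) and IDI1 at 0.32 (SE 0.04), and PDGFA at -0.48 (SE 0.05), DNM2 at -0.50 (SE 0.06) and SIPA1L3 at -0.61 (SE 0.07). The other higher genes, between 0.23 and 0.34, were AGR2, ELOC, TMEM126B, GSKIP, ESCO2 (a cohesin acetyltransferase), APOH, CENPW, THOC7 and LSM5. The other lower genes, between -0.52 and -0.32, were TUBB2A, CDC37, STARD10, H2AC15, ZFAND2B, MBOAT7, DGAT1, CCN1 and SLC29A4. All had an adjusted p of 0.437. As the mean of their 2 probe sets, PARGP1 was at 0.22, ELOC at 0.08 and TUBB2A at -0.20. The sign of IDI1, AGR2, ELOC, CENPW, THOC7 and LSM5 turned with the values as deposited and with median centring, and that of APOH with median centring. CYP24A1 was at -0.82 (SE 0.25) and VDR at -0.04 (SE 0.04), a mean over labels that CYP24A1 sets apart.

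No list passed for the mean of both ligands, with the smallest adjusted p at 0.188 for acute phase proteins and for hepatocyte markers. With the values as deposited and with median centring, cholesterol synthesis, fatty acid synthesis, cell cycle, p53 targets, unfolded protein response, hepatitis C virus host factors and immediate-early genes passed with lower values in the ligand groups. Adjusted over the list alone, RXRA (-0.26, SE 0.05), FGFR4 (-0.48, SE 0.08), ACADVL (-0.28, SE 0.05), DGAT1, CCN1, APOH, ALB and 4 cholesterol genes passed, among them SREBF2 (-0.28, SE 0.06). ALB was at 0.25 (SE 0.06), or -0.10 with the values as deposited and -0.19 with median centring. In fry, 7 lists changed in either direction and 0 on balance one way. Limma called 0 genes, and 1370 had an unadjusted p under 0.05, 595 higher and 775 lower, where 920 are expected by chance. The split was 520 and 1631 with the values as deposited, and 787 and 1939 with median centring. Complete separation held for 16% of genes against 13.3% by chance. With a variance trend 1 gene passed, PCDHA3 (-0.28, adjusted p = 0.0387). An unadjusted p under 0.01 with at least 1.5-fold held for 3 genes, SIPA1L3, NTS and GRN (-0.60, SE 0.15), the last named after its value was seen.

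Across genes, which are not independent replicates, the fold changes of both ligands against mock correlated with Pearson's r = 0.378 and Spearman's rho = 0.346. Simulated unchanged groups against the same mock arrays gave r = 0.419. The covariance was 0.00411 against 0.00318 simulated, a difference of 0.00093. The simulated covariance rests on the spread of 1 pair of arrays, and the replicate variance of a group mean ran from 0.00259 in calcipotriol to 0.00681 in calcitriol, so this difference has no firm sign. With 2 mock arrays the controls could not be split with 2 in each part, so some or all of the correlation may come from the shared arrays. The simulated r was in fact above the observed one. The value of r was 0.0717 without calcitriol replicate 1, 0.634 without calcitriol replicate 2, and 0.784 with the values as deposited or with median centring. Both scalings keep the spreads of the deposited arrays, which were narrower in the ligand arrays (SD 0.753 to 1.09) than in mock (1.14 and 1.15). No simulated r was computed for these scalings, so 0.784 is not shown to reflect the ligands.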

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

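The VDR list without CYP24A1 and SLC30A10, the block with crossed numbers and the other scalings of the correlation of the differences from calcipotriol were chosen after seeing the data, and the other alternatives before. Limma called 0 genes in each comparison under every alternative run for it (only the groups compared was not run for the mean of both) except the variance trend, which called 2 for calcitriol against mock, 0 for calcipotriol against mock, 1 for calcipotriol against calcitriol and 1 for the mean of both, and the unadjusted p under 0.01 with 1.5-fold, which by construction skips the adjustment and took 4, 29, 5 and 3. Leaving out each array gave 0 genes each time (lowest 0, highest 0), where the lone array left in a group is assumed to vary like the others. CYP24A1 passed with the variance trend at -1.85 (adjusted p = 0.0280) for calcitriol against mock and at 2.06 (0.00837) between the ligands. The cause was not tested.

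For calcitriol against mock, lists called were 14 with the values as deposited and 10 with median centring, and 0 to 1 with an array left out (cell cycle, without mock replicate 2). For calcipotriol against mock they were 5, 3 and 0 to 1, and 0 with an estimated correlation and with fry. For calcipotriol against calcitriol they were 9 with each scaling, 0 to 4 with an array left out, and 0 with an estimated correlation, fry or the shorter VDR list. For the mean of both ligands they were 12 with the values as deposited and 7 with median centring. Both scalings leave the unlike spreads of the arrays in place, and reference genes were among the lists called for calcitriol against mock and between the ligands with both, and for the mean of both with the values as deposited. Without dim genes, 2 lists were called between the ligands, acute phase proteins and glucose metabolism. The cause was not tested.

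The correlation of the ligands' fold changes was 0.784 with either scaling, for which no simulated value was computed, and 0.0717 to 0.634 with an array left out. The correlation of the differences of mock and calcitriol from calcipotriol turned from 0.724 to -0.1136 with either scaling. Too few genes passed to compute the first over called genes. CYP24A1 in calcipotriol against mock was -0.0298 with median centring and -0.230 to 0.654 with an array left out, its calcitriol against mock value stayed between -2.23 and -1.35, and that between the ligands between 1.85 and 2.28.

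The replicate numbers did not pair the arrays (correlation of same-numbered deviations -0.08, 0.03 and -0.41). With the replicate number as a block, 0 genes were called in every comparison and the lists called were 0, 1, 0 and 0 (0 between the ligands, with adjusted p = 0.0703 for VDR targets and for drug metabolism and 0.0504 for acute phase). With the calcipotriol numbers crossed, the block gave 0 genes between the ligands.

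Of 2379 alternative values of 151 fold changes of named genes other than CYP24A1 in its pairwise comparisons, 2345 kept their direction and side of the threshold, 2 passed (PCDHA3 for calcitriol and for the mean of both against mock, variance trend) and 32 changed sign, all with the values as deposited or median centred. Most alternatives could not turn a sign, as they change only the error or the genes tested. Genes named by the rule separate the arrays completely, so leaving out 1 array can hardly turn them. The sign was thus tested mainly by the scalings, where 12 of 151 turned with the values as deposited and 20 of 151 with median centring. For calcitriol against mock with median centring, FN3KRP was -0.0688, MEST -0.0570, SNORD116-6 -0.21, MORF4L1 -0.44, EI24 -0.0906, CLRN3 -0.27, NDFIP1 -0.0325, VDR -0.0623, ALB -0.53 and CDK1 -0.19, and with the values as deposited SNORD116-6 was -0.10, MORF4L1 -0.33, CLRN3 -0.16, ALB -0.42 and CDK1 -0.0736. Between the ligands with median centring, CDC20 was 0.0406 and TUBB2A 0.0510. For the mean of both with median centring, IDI1 was -0.10, AGR2 -0.18, ELOC -0.22, APOH -0.0471, CENPW -0.14, THOC7 -0.13, LSM5 -0.12 and ALB -0.19, and with the values as deposited IDI1 was -0.0117, AGR2 -0.0905, ELOC -0.13, CENPW -0.0518, THOC7 -0.0415, LSM5 -0.0374 and ALB -0.10. The cause was not tested. Signal over background limits dim genes, since 11147 of the 18404 genes lay above the median of all probe sets (6.21) and no background value was analysed here.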

Other observations

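The tests of an exchange of labels against CYP24A1 and SLC30A10 and of the narrow range of calcitriol replicate 2, the wider bound on the covariance across genes, and the correlation across genes with another scaling, were chosen after the result was seen, and the other tests before.

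After quantile normalization, the differences of mock and of calcitriol from calcipotriol correlated across genes with r = 0.724, where unchanged groups against the same calcipotriol arrays gave 0.351, and their covariance of 0.0106 exceeded the simulated 0.00259 and also the replicate variance of the mean in the most variable group, calcitriol (0.00681). With the values as deposited the correlation was -0.114 and the covariance -0.00331, so the pattern depends on the scaling. Median centring cannot change these values, as it shifts all genes of an array alike. Both of these scalings keep the unlike spreads of the arrays. The replicate variance of the calcitriol mean was 0.0328 as deposited and 0.0439 with median centring, against 0.00681 after quantile normalization. A larger replicate variance also widens the errors behind the counts that follow. Where 920 genes are expected by chance, 99 had an unadjusted p under 0.05 between the ligands with the values as deposited and 58 with median centring, and between calcipotriol and mock 1348 and 1544 did. Single arrays went partly with the pattern. Calcitriol replicate 1 correlated with the mock arrays at 0.9926 and 0.9933, above the mock pair (0.9921), but with calcipotriol replicate 1 at 0.993, like the calcipotriol pair. Calcitriol replicate 2, with the lowest mean correlation (0.983), correlated with the mock arrays at 0.9851 and 0.9854 and with the calcipotriol arrays at 0.9844 and 0.9763. CDC37, BIN1, STARD10, ANKRD52 and TUBB2A were among the lower genes, and LAMP2, PFDN4, APOH and GGH among the higher ones, of the rule in calcipotriol against mock and also against calcitriol. Both comparisons share the calcipotriol arrays, so some genes recur without any effect, and no chance overlap was computed. TUBB2A against calcitriol turned to 0.0510 with median centring. None of these passed the adjusted threshold. The labels give no batch, so a technical difference of this pair of arrays was not tested.

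CYP24A1 and SLC30A10 were low in both arrays labelled calcitriol and high in the arrays labelled mock and calcipotriol. The narrow range of calcitriol replicate 2 does not account for the low CYP24A1, which stayed at -2.05 against mock without that array. The sign of SLC30A10 did not turn without it either, but its size was not part of this test. An exchange of the mock and calcitriol labels, in the table or at the bench, is a candidate explanation, because a mock sample should have little CYP24A1 and a calcitriol sample much. The other 41 VDR targets do not decide it, as their median for mock minus calcitriol lay at percentile 92.18 of brightness-matched lists, inside the central 95% of those lists. Their median for calcipotriol minus calcitriol, a difference that shares the calcitriol arrays, lay at percentile 93.2, also inside that range. The exchange therefore cannot be told apart from a true fall of both genes, and no biological explanation for such a fall was tested. With the labels as they stand, CYP24A1 also did not clearly rise in calcipotriol against mock (0.21, limma, adjusted p = 0.896). Without an exchange, a fall with calcitriol and no clear rise with calcipotriol would both need an explanation.

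Differences across all genes do not decide on an exchange either. If it held and both ligands acted on many genes alike, mock minus calcitriol and calcipotriol minus calcitriol would share more than the chance covariance, and the difference from the simulated covariance was -0.00285. By the bound set beforehand, 2 SD of the simulations (SD 0.000159), this value would have counted against the exchange. That bound was wrong, since the simulated value takes the replicate variance of the calcitriol mean (0.00681) from 1 pair of arrays as if it were known. The bound was widened after the value was seen to the range of the 3 groups (0.00259 to 0.00681), and the observed 0.00395 lies inside it, so the exchange stays open. Of the 15 groupings of the 6 arrays into 3 pairs, 3 reached 1469 genes with an unadjusted p under 0.05 in limma's F-test, the labelled one (1469) and 2 others (1770 and 2400), both of which kept the calcipotriol pair and mixed mock with calcitriol. With 15 groupings the share cannot fall under 0.05.

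Acute phase proteins passed camera with higher values in the arrays labelled calcipotriol than in mock at the preset correlation (0.0218) and not with an estimated one (adjusted p = 0.653), and 0 of its 21 measured genes passed over all genes. The call was also lost without mock replicate 2 (0.0525), calcipotriol replicate 1 (0.0544) or calcipotriol replicate 2 (0.0696). It held without dim genes (0.0172), with the replicate number as a block (0.0187), and without mock replicate 1 or either calcitriol array. The brightness of these genes does not account for the call, since the list's median was at percentile 99.24 of brightness-matched lists, and at 99.95 against calcitriol, with 49.3 for calcitriol minus mock. The scaling of the arrays stays open as an explanation, because with the values as deposited the list's adjusted p was 0.423 against mock and 9.61e-06 against calcitriol, and with median centring 0.507 and 0.00232. An effect of calcipotriol stays open too, as a hypothesis that these 2 arrays per group cannot settle.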
